A study of Homo sapiens with 12 samples.

How the data were processed

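RNA was measured in 12 libraries of G401, a human malignant rhabdoid tumour cell line, in 4 groups of 3. The cells carried a control hairpin (shCTRL) or a hairpin against DCAF5 (shDCAF5), each in cells with SMARCB1 put back (SMARCB1+) or, per the sample titles, with GFP instead. Per the labels, all cells grew in McCoy's medium with tetracycline-free serum, 1 µg/ml puromycin and 1 µg/ml doxycycline, and each sample is labelled 72 h. The labels do not say which construct doxycycline controlled, nor whether the replicates are separate cultures. Per the labels' protocols, RNA was extracted with a Zymo Direct-zol kit and libraries were made with the TruSeq Stranded mRNA kit, which marks strand. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.3 and the genome was hg19 (GRCh37.p13). The deposited table holds expected counts per gene, with 1 column per library and no normalization. RSEM is named by the table's title alone; the aligner and the RSEM version are not given in the sources used here. Between 2.59% and 3.12% of the values per library were not whole numbers. The columns were matched to the samples by name, with 0 left over, and the 92 spike-in entries summed to 0 counts. Totals ran from 46384130 to 97237162 expected counts per library.

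For the tests, expected counts were rounded to whole numbers and genes with few counts were removed with filterByExpr by group, which left 18360 of 57820 genes. Libraries were scaled with TMM. All 12 libraries were fitted together in edgeR 4.0.16 (R 4.3.3), with 1 mean per group, and contrasts were tested with its quasi-likelihood F test. P-values were adjusted with the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Single-gene adjusted p-values below are from this edgeR test. The contrasts were shDCAF5 against shCTRL, shCTRL_SMARCB1+ against shCTRL, shDCAF5_SMARCB1+ against shCTRL_SMARCB1+, shDCAF5_SMARCB1+ against shDCAF5, shDCAF5 against shCTRL_SMARCB1+, and the interaction, which is the knockdown effect with SMARCB1 minus that without it. Standard errors (SE) are those implied by the fold change and its F statistic. Levels are CPM, as edgeR's cpm function computes them from the TMM-scaled totals, with the standard deviation (SD) over 3 libraries. For genes with at most 3 counts over a group, ratios of summed counts per summed total are given with a 95% exact Poisson interval, and against 0 counts as a lower bound at 3 counts over the group. Such intervals and bounds cover counting error only. The medians of the lists named below did not move with such genes held at their bounds (largest change 0).

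Genes were named by a rule fixed, like the contrasts, the gene lists and most alternatives, before the data were examined. It takes DCAF5 and SMARCB1, and the 10 largest rises and falls of the first 3 contrasts among called protein-coding genes with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries. It takes 5 and 5 for shDCAF5 against shCTRL_SMARCB1+ and for the interaction, the latter without the overlap condition. It adds up to 4 members of each list called, by smallest p, the 10 shared rises and falls with the largest smaller change, and the SWI/SNF subunits.

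The 28 gene lists, written from general knowledge, were SWI/SNF subunits, CUL4 ligase and DCAF genes, Polycomb subunits, DNA replication and E2F targets, mitosis genes, CDK inhibitors and p53 targets, MYC targets and ribosome biogenesis, cytosolic ribosomal proteins, mitochondrial DNA encoded genes, contractile and smooth muscle genes, YAP targets, collagens and extracellular matrix, epithelial genes, neural and neuronal genes, kidney and nephron progenitor genes, skeletal muscle genes, neural crest genes, HOX genes, interferon response genes, AP-1 and immediate early genes, unfolded protein and integrated stress response, hypoxia and glycolysis genes, cholesterol biosynthesis genes, inflammatory cytokine and NF-kB genes, Hedgehog and Wnt targets, replication-dependent histone genes, and, as markers of other cells, blood and immune cell markers and endothelial markers. Each was tested against the other genes with camera (limma 3.58.1, preset correlation 0.01, log2 CPM with a prior count of 2) in the first 3 contrasts and the interaction, adjusted over all 112 tests. Camera with an estimated correlation and fry were the alternatives; fry asks whether a list's genes move on balance 1 way, not whether they differ from other genes. Members were counted as called over all genes and as adjusted over the list alone.

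Transcript GC content and 3' UTRs came from GENCODE v29, matched by gene ID, since no annotation of the authors' build was at hand; 17707 of the genes tested (96.4%) had a GC value, and no coordinates were used. Each library's GC slope was fitted over genes with a mean log2 CPM of at least 4. Because libraries of 1 group differed in this slope, GC-content corrections were added after the data were seen: per-library loess curves (span 0.4, genes with a mean log2 CPM of at least 2) removed as offsets, and the GC slope as a covariate. Other settings were chosen in advance: RLE and upper quartile scaling, no filter, a strict filter at a mean of 5 CPM, DESeq2 1.42.0, limma-voom, unrounded values, the replicate number as a block, only the groups compared, protein-coding genes only, and each library left out in turn. Replicate numbers were not treated as pairs: of 18 comparisons of libraries with the same number, 7 had a correlation of their deviations above 0.1 (range -0.98 to 0.88), and 1 library of 12 was closest to its own number.

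Overlaps of contrasts that share the shCTRL libraries were set beside the overlap of independent lists, and the correlation of their fold changes beside 20 simulations of unchanged groups. Other splits of the libraries were refitted, all 10 for 3 against 3 and 100 drawn for the interaction. For motifs, each sequence of 7 bases present in at least 100 genes was scored in annotated 3' UTRs of at least 50 bases of protein-coding genes with a mean of at least 5 CPM (9558 genes, 15622 sequences), with GC-corrected log2 fold changes limited to an absolute value of 2 and adjusted for UTR length and base composition, beside the 95% limit of 200 permutations. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 ran this step and the plots.

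The edgeR test, camera and the motif step were tested on simulated or permuted data, for shDCAF5 against shCTRL alone. Other contrasts and other steps were not tested in this way. For shDCAF5 against shCTRL (17982 genes), edgeR recovered 18.2%, 80.6% and 98.5% of genes changed by 0.5, 1 and 2 log2 units, and 2.94% of its calls were false. With the measured GC curves added (17340 genes) it recovered 16.7%, 70.1% and 98.5% without correction, with 0 false calls, and 75.8%, 97% and 100% with GC-content offsets, with 5.21% of calls false. These curves were fitted by the same correction that then removed them, and the simulated spread was that left after it. The gain with the offsets is therefore built in and does not show how well they suit the real libraries. For the same contrast (18360 genes) camera called 3 of 3 lists lowered by 0.5 and 0 of the others, and the motif step found 5 of 5 planted sequences at a lowering of 0.2. The planted sequences were carried by more genes than TGTCCGA, the main motif named below, which 155 genes carried. How the step finds rarer sequences or smaller shifts was not tested. Genes in the camera simulation varied independently, so it does not show how the preset correlation performs where genes vary together.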

Results

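Poly(A) RNA of G401 cells was sequenced in 12 libraries, 3 for each of shCTRL, shDCAF5, shCTRL_SMARCB1+ and shDCAF5_SMARCB1+. G401 derives from a malignant rhabdoid tumour, a childhood cancer driven by loss of SMARCB1, a core subunit of SWI/SNF chromatin remodelling complexes. DCAF5 is a substrate receptor of CUL4-DDB1 ubiquitin ligases. Totals of expected counts were 87766759, 88777599 and 73483485 in the shCTRL libraries (replicates 1, 2 and 3) and 97237162, 90765985 and 94378208 in shDCAF5. They were 80826012, 89757471 and 91776534 in shCTRL_SMARCB1+ and 90240640, 79422459 and 46384130 in shDCAF5_SMARCB1+. Between 22812 and 24816 genes had a count per library, and transcripts of mitochondrial DNA took 9.64% to 12.1%.

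Presence of SMARCB1 separated the libraries along the first principal component, with 72.3% of the variance. The second component, with 13.2%, followed transcript GC content (loadings correlated with GC at 0.82 across 7511 genes). GC slopes, in log2 units per 10 points of GC content, ran from -0.298 to 0.2 within shCTRL, -0.318 to 0.226 within shDCAF5, 0.116 to 0.398 within shCTRL_SMARCB1+ and -0.2 to 0.042 within shDCAF5_SMARCB1+. Across these genes, log2 fold changes correlated with GC content at -0.16 for shDCAF5 against shCTRL, 0.33 for shCTRL_SMARCB1+ against shCTRL, -0.71 for shDCAF5_SMARCB1+ against shCTRL_SMARCB1+ and -0.69 for the interaction; genes are not independent replicates. Whether the replicates are independent cultures is not known, so p-values measure the spread between these libraries, which may be technical.

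DCAF5 was lower in all 6 libraries with its hairpin than in any control library. Its mean level was 75.03 ± 1.92 CPM (SD, n = 3) in shCTRL and 46.88 ± 1.98 CPM in shDCAF5, or 62.5% of control (log2 fold change -0.68, SE 0.06, edgeR adjusted p = 0.00019). With SMARCB1 it was 73.65 ± 3.8 CPM in shCTRL_SMARCB1+ and 36.14 ± 0.643 CPM in shDCAF5_SMARCB1+, or 49.1% of control (log2 fold change -1.03, SE 0.06, edgeR adjusted p = 1.7e-05). The effects differed by -0.35 (SE 0.09, edgeR adjusted p = 0.11), a difference called by DESeq2 (-0.32, adjusted p = 0.0087) and by edgeR with GC-content offsets (-0.29, adjusted p = 0.0063) or the GC slope covariate (0.0041), while the other alternatives gave edgeR or limma-voom adjusted p-values of 0.11 to 0.36. SMARCB1 itself had 0 counts in 5 of the 6 libraries without it and 75 counts (1.075 CPM) in shCTRL replicate 3. It reached 3984 ± 742 CPM in shCTRL_SMARCB1+ and 3110 ± 316 CPM in shDCAF5_SMARCB1+. The ratio of shCTRL_SMARCB1+ to shCTRL, 14000 (counting interval 11200 to 17800), rests on that 1 library. Without shCTRL replicate 3 there were 0 counts, and the bound was at least 247000-fold. In shDCAF5_SMARCB1+ it was at least 299000-fold above shDCAF5. Between the groups that carry it, SMARCB1 differed by -0.36 (SE 0.55, edgeR adjusted p = 0.65). Yet each shDCAF5_SMARCB1+ library (2827 to 3451 CPM) lay below each shCTRL_SMARCB1+ library (3480 to 4836 CPM). The fit uses 1 spread per gene over all libraries, among them those with 0 or 75 counts. This test therefore does not exclude a lower SMARCB1 level, which would be part of the comparisons of these groups.

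**Figure D1:**
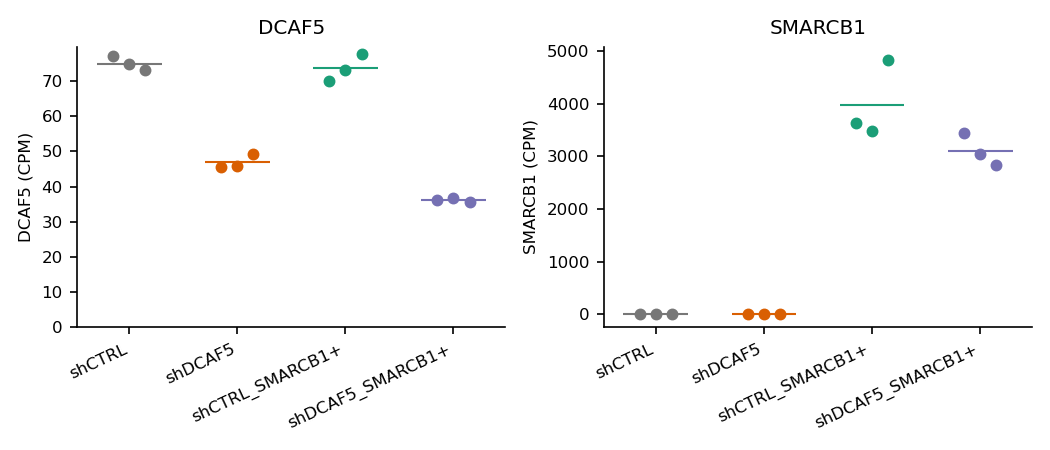
DCAF5 and SMARCB1 levels in CPM (vertical axes) by group (horizontal axes); points are single libraries and lines are means of 3. DCAF5 averages 75.03 CPM in shCTRL and 46.88 CPM in shDCAF5, and SMARCB1 is near 0 in the 6 libraries without it.

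What DCAF5 knockdown changes in cells that lack SMARCB1 was asked with shDCAF5 against shCTRL. Genes of DNA replication and of mitosis had medians of -0.48 and -0.45 log2 units, with 25 of 48 and 21 of 44 called lower. Of genes of the extracellular matrix, of the interferon response and of replication-dependent histones, 8 of 43, 6 of 40 and 4 of 17 were called higher. Limma camera called these 5 lists with its preset correlation and none with an estimated one (adjusted p 0.19 to 0.806). Among single genes, GALNT16, which starts O-linked glycans, went from 2.12 to 9.24 CPM, and DRAXIN, a secreted guidance factor for growing axons, went from 21.6 to 7.46 CPM. JUN, a subunit of the AP-1 transcription factor, fell from 5.27 to 2.64 CPM. EdgeR called 760 genes up and 543 down of 18360, of which 153 and 54 changed at least 2-fold.

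The largest rises were GALNT16 (log2 fold change 2.12, SE 0.19, edgeR adjusted p = 0.00013), the ADP-ribosyltransferase gene ART5 (1.81), SCRG1 (1.69) and SPOCD1, known for germline DNA methylation (1.63, from 13.4 to 41.3 CPM). Next were the amino acid transporter SLC7A8 (1.48), the matrix protein matrilin MATN2 (1.47), EVI5L (1.43), the dynein light chain DYNLRB1 (1.40), the lipid flippase ATP8B1 (1.39) and LRRC15 (1.37). The largest falls were DRAXIN (-1.53, SE 0.12, edgeR adjusted p = 6.3e-05), the smooth muscle calponin CNN1 (-1.38), the cardiac troponin TNNT2 (-1.37) and the matrix glycoprotein thrombospondin THBS1 (-1.26). PITHD1 (-1.15), the respiratory complex I assembly factor TIMMDC1 (-1.06), PSG6 (-1.02), JUN (-1), SRCRB4D (-0.99) and the channel protein PANX1 (-0.98) followed. PSG6 belongs to a family of near-identical pregnancy-specific glycoproteins, so its count is uncertain. DRAXIN, TIMMDC1, PANX1 and JUN carry the sequence TGTCCGA in an annotated 3' UTR (GENCODE v29). The call of CNN1 ended without shCTRL replicate 1 or 2 or shDCAF5 replicate 1 or 2 (edgeR adjusted p 0.065 to 0.091), and that of SRCRB4D without shCTRL replicate 2 or shDCAF5 replicate 1 or 2 (0.05 to 0.069). That of EVI5L held only without shCTRL replicate 1, shDCAF5 replicate 1 or shCTRL_SMARCB1+ replicate 2 or 3, and its edgeR adjusted p was 0.054 to 0.15 without any other library.

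Replication genes stood out in shDCAF5 libraries: of 48 measured, 0 rose, 25 fell and 23 did not pass (37 lower adjusted over the list alone), with 47 of 48 below shCTRL (limma camera adjusted p = 4.38e-25; adjusted p = 0.19 with an estimated correlation). Examples were GINS4 (-0.90, from 56.7 to 30.3 CPM) and CDC45 (-0.75), both parts of the replicative helicase, the helicase subunit MCM4 (-0.54) and the polymerase subunit POLA2 (-0.53). Mitosis genes behaved alike, with 0 up, 21 down and 23 not passing of 44 (38 lower adjusted over the list alone), and all 44 lower (camera adjusted p = 4.38e-25; adjusted p = 0.348 with an estimated correlation). The kinesin KIF20A (-0.62, from 105 to 68.2 CPM), the spindle protein PRC1 (-0.56), the ubiquitin-conjugating enzyme UBE2C (-0.51) and CDCA8, of the chromosomal passenger complex (-0.66), were among them. MYC targets and ribosome biogenesis genes had a median of -0.14 with 38 of 40 members lower and 0 called (camera adjusted p = 0.00433; adjusted p = 0.751 with an estimated correlation). MRTO4 (-0.31), NOP56 (-0.22), GNL3 (-0.29) and RCL1 (-0.15) had the smallest p-values there, with edgeR adjusted p of 0.085 to 0.27. By limma fry MYC targets had an adjusted p of 0.104.

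Matrix genes were higher by a median of 0.24, with 8 up, 1 down and 34 not passing of 43 (10 and 1 adjusted over the list alone; camera adjusted p = 0.0229; adjusted p = 0.806 with an estimated correlation). The fibrillar collagen COL5A2 (0.76) and the microfibril protein FBN1 (0.52) rose, and THBS1 fell. Interferon response genes had a median of 0.19, with 6 up and 0 down of 40 (8 and 0 adjusted over the list alone; camera adjusted p = 0.0229; adjusted p = 0.574 with an estimated correlation). The ADP-ribosyltransferase PARP9 (0.76), the restriction factor TRIM22 (0.54) and the ISG15 protease USP18 (0.68) rose; OASL, with 1 count in shCTRL, was 22.1 times higher (counting interval 3.97 to 874). Replication-dependent histone genes, whose copies share reads, had a median of 0.43, with 4 up and 0 down of 17 (5 and 0 adjusted over the list alone; camera adjusted p = 0.00433; adjusted p = 0.655 with an estimated correlation). Those called were HIST1H2AG (0.85), HIST2H2BE (0.55), HIST1H2BK (0.46) and HIST1H2BD (0.49). Only poly(A) RNA was sequenced, so histone transcripts without a poly(A) tail are not covered by these values. The call of HIST1H2BD ended without any library but shCTRL_SMARCB1+ replicate 3 (edgeR adjusted p 0.057 to 0.13), and that of HIST1H2BK without shCTRL replicate 1 or 2 or shDCAF5 replicate 1 or 2 (0.052 to 0.098) and with GC-content offsets (0.14). That of HIST2H2BE ended by edgeR without shCTRL replicate 1 or 2 (0.055 and 0.062) and that of TRIM22 without shCTRL replicate 2 (0.056). Without shCTRL replicate 3 or shDCAF5 replicate 3, camera adjusted p-values were 0.192 and 0.357 for matrix genes, 0.0682 and 0.205 for interferon genes and 0.0594 and 0.182 for histone genes, and with GC-content offsets interferon genes had 0.0512. By limma fry matrix genes had an adjusted p of 0.164.

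SWI/SNF subunits did not shift as a list (25 measured, median -0.02, camera adjusted p = 0.847). SS18, a subunit altered in synovial sarcoma, rose (0.70, edgeR adjusted p = 0.0035). SMARCD1 fell (-0.36, edgeR adjusted p = 0.011), a call that ended without shCTRL replicate 2 or shDCAF5 replicate 1 or 2 (0.059 to 0.071). Medians of the lists not called by camera were 0.01 for CUL4 ligase and DCAF genes, -0.02 for Polycomb subunits, -0.02 for CDK inhibitors and p53 targets, 0.02 for cytosolic ribosomal proteins, 0.03 for mitochondrial DNA encoded genes, -0.06 for contractile and smooth muscle genes and 0.10 for YAP targets. They were 0.22 for epithelial genes, 0.28 for neural and neuronal genes, -0.12 for kidney and nephron progenitor genes, -0.02 for skeletal muscle genes, 0.03 for neural crest genes, -0.02 for HOX genes, 0.10 for AP-1 and immediate early genes and 0.08 for the unfolded protein and integrated stress response. Hypoxia and glycolysis genes had 0.05, cholesterol biosynthesis genes -0.02, inflammatory cytokine and NF-kB genes 0.04, Hedgehog and Wnt targets -0.08, blood and immune cell markers 0.11 and endothelial markers 0.15. Camera adjusted p-values of these lists were 0.059 (neural genes) or higher; with GC-content offsets neural genes had 0.0284, and 0.36 with an estimated correlation. For endothelial markers, whose median was above 0, the mean was -0.14.

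Left-out libraries and other settings moved the number of genes called for shDCAF5 against shCTRL by more than 1.5 times. There were 1299 up and 875 down without shDCAF5 replicate 3, against 330 and 202 without shCTRL replicate 2, 352 and 201 without shDCAF5 replicate 2, 434 and 297 without shDCAF5 replicate 1, and 450 up without shCTRL replicate 1; GC-content offsets gave 2371 and 2087, among them 727 and 510 of those called here. With only the groups compared, edgeR calls ended for CDC45 (adjusted p = 0.06), POLA2 (0.059), USP18 (0.087), SS18 (0.06), TMEM97 (0.068), YBX2 (0.06) and MMRN2 (0.093). They also ended there for EVI5L, CNN1, SRCRB4D, NAA30, SMARCD1, TRIM22, HIST2H2BE, HIST1H2BK and HIST1H2BD (edgeR adjusted p 0.07 to 0.17), and without a filter for HIST1H2BD (0.077).

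**Figure D2:**
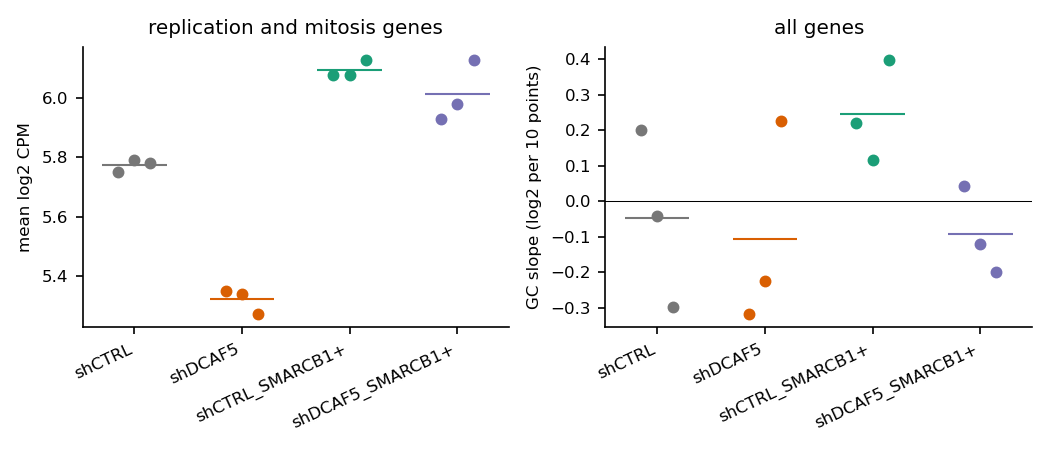
Left, mean log2 CPM of 92 replication and mitosis genes, and right, GC slope of all genes in log2 units per 10 points of GC content, by group on the horizontal axes; points are single libraries and lines are means of 3. The 3 shDCAF5 libraries have the lowest replication and mitosis means, and GC slopes differ within groups, from -0.298 to 0.2 in shCTRL.

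SMARCB1 re-expression with the control hairpin, shCTRL_SMARCB1+ against shCTRL, changed far more genes. Of 43 matrix genes 30 were called higher and 8 lower, and limma camera called the list higher (adjusted p = 3.26e-05; adjusted p = 0.691 with an estimated correlation). The laminin chain LAMB1 went from 3.44 to 549 CPM, the collagen chain COL4A5 from 0.438 to 153 CPM and the matrix protein SPARC from 215 to 3610 CPM, while the laminin chain LAMA4 fell from 75.6 to 0.987 CPM. Camera called contractile, epithelial, endothelial, HOX and hypoxia genes higher and ribosomal protein and mitochondrial DNA encoded genes lower, but none of these lists with an estimated correlation (adjusted p 0.451 to 0.85). With GC-content offsets the calls of epithelial, endothelial, HOX, hypoxia and mitochondrial genes ended. SMARCA2, the alternative ATPase of SWI/SNF, which had 2 counts over shCTRL, was 62.9 times higher (counting interval 17.4 to 519). EdgeR called 4495 genes up and 4189 down, of which 2312 and 1286 changed at least 2-fold (n = 3 per group).

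Besides SMARCB1, the largest rises were CPA4, a carboxypeptidase (0.0184 to 42.3 CPM), the formin DIAPH2 and the synaptic adhesion protein NLGN1. They included NT5E, which makes adenosine outside cells (0.0499 to 46.2 CPM), the neuropeptide receptor NPFFR2, the G protein subunit GNG11, the basement membrane collagen COL4A6 (0.0745 to 49.4 CPM), ARSD (0.0243 to 14.7 CPM) and the proprotein convertase PCSK6 (0.0456 to 24.1 CPM). With 2 counts over shCTRL, DIAPH2 was 2190 times higher (counting interval 605 to 18100), NPFFR2 859 times (238 to 7090) and GNG11 852 times (236 to 7030). NLGN1, with 3 counts, was 1950 times higher (668 to 9470). Among the largest falls were the glutathione transferase MGST1, which had 1 count over shCTRL_SMARCB1+ and was 16200 times higher in shCTRL (2900 to 639000), and GRAMD3 and the zinc finger gene ZNF69, at least 666-fold and 653-fold lower. The synaptic scaffold DLGAP2 was 2120 times higher in shCTRL (586 to 17500). GPM6B, a neural membrane protein (19.2 to 0.0218 CPM), the calcium-binding S100A6 (39.6 to 0.0744 CPM), the secreted peroxidase GPX3 (29.1 to 0.0711 CPM), LINC00923 (5.2 to 0.0148 CPM), ARMCX2 (9.42 to 0.0292 CPM) and the transcription factor KLF7 (55.2 to 0.215 CPM) completed them. EdgeR adjusted p-values of these genes were 2.9e-06 or lower. A count made after the values were seen found 13 genes at 5 CPM or more in both groups with SMARCB1 and under 0.1 CPM in both without, 11 genes the other way round, and 0 genes split in this way by the hairpin. Cells with and without SMARCB1 carried different vectors, so any other difference between those cultures is part of this comparison.

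Matrix genes had a median of 1.24, with 30 up, 8 down and 5 not passing of 43 (33 and 8 adjusted over the list alone; camera adjusted p = 3.26e-05; adjusted p = 0.691 with an estimated correlation). Contractile genes had 18 up and 3 down of 25 (median 0.92; camera adjusted p = 0.00989; adjusted p = 0.793 with an estimated correlation). Smooth muscle actin ACTA2 (2.50) and the myosin MYH10 (0.58) rose, while vinculin VCL (-0.90) and caldesmon CALD1 (-1.54) fell. Of 23 epithelial genes 13 rose and 3 fell (median 0.80; camera adjusted p = 0.0171; adjusted p = 0.451 with an estimated correlation). They included E-cadherin CDH1 (0.211 to 2.65 CPM), LAMB3 (5.46), CDS1 (2.60) and GRHL1 (1.73). HOX genes, which pattern the body axis, had 20 up and 3 down of 35 (median 0.32; camera adjusted p = 0.00723; adjusted p = 0.467 with an estimated correlation). Examples were HOXB9 (1.87), HOXD3 (3.77), HOXA13 (2.40) and HOXB8 (1.48). Endothelial markers had 6 up and 1 down of 9 (median 2.25; camera adjusted p = 0.0455; adjusted p = 0.451 with an estimated correlation), but at low levels. ESAM went from 0.154 to 0.919 CPM, TIE1 from 0.0233 to 1.02 CPM and VWF from 0.514 to 2.48 CPM, while the abundant MMRN1 fell from 578 to 180 CPM.

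Metabolic and stress genes followed. Hypoxia and glycolysis genes had 17 up and 4 down of 32 (median 0.41; camera adjusted p = 0.00723; adjusted p = 0.628 with an estimated correlation). The glucose transporter SLC2A3 went from 101 to 573 CPM and its relative SLC2A1 from 319 to 51.7 CPM. PDK1, which holds back pyruvate dehydrogenase (2.91), and PFKFB3, which drives glycolysis (1.62), rose. In the unfolded protein and integrated stress response, 18 rose and 3 fell of 34 (median 0.38; camera adjusted p = 0.0166; adjusted p = 0.348 with an estimated correlation). The lipoprotein receptor VLDLR (5) and TRIB3 (2.17) rose, and DDIT4 (-1.27) and the serine synthesis enzyme PSAT1 (-1.30) fell. Inflammatory genes had 10 up and 3 down of 22 (median 0.33; camera adjusted p = 0.0383; adjusted p = 0.751 with an estimated correlation). Examples were IGFBP7 (8.93 to 353 CPM), TNFAIP3, an inhibitor of NF-kB (2.46), the cytokines IL11 (1.55) and, near the detection limit, IL1A (0.0161 to 0.61 CPM). Hedgehog and Wnt targets had 10 up and 3 down of 18 (median 0.58; camera adjusted p = 0.025; adjusted p = 0.751 with an estimated correlation). CCND2 (4.51), AXIN2 (1.71) and the receptor FZD7 (2.06) rose and the secreted Wnt inhibitor DKK1 fell from 230 to 3.28 CPM.

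Replication genes had 25 up and 4 down of 48 with SMARCB1 (median 0.33; camera adjusted p = 0.011; adjusted p = 0.751 with an estimated correlation). MCM6 (0.80), POLA2 (0.64) and GINS2 (0.59) rose, and the cyclin CCNE1 fell (-0.52). Mitosis genes had 20 up and 0 down of 44 (median 0.26; camera adjusted p = 0.00433; adjusted p = 0.806 with an estimated correlation), such as the proliferation marker MKI67 (0.78), CDCA3 (0.99), CDCA8 (0.69) and BIRC5 (0.51). MYC targets and ribosome biogenesis genes had 3 up and 16 down of 40 (median -0.21; camera adjusted p = 0.0445; adjusted p = 0.806 with an estimated correlation). Nucleolin NCL (-0.56), NOLC1 (-0.70) and WDR12 (-0.73) fell and ODC1, of polyamine synthesis, rose (0.58). Ribosomal proteins had 0 up and 21 down of 61 (median -0.07; camera adjusted p = 0.0307; adjusted p = 0.85 with an estimated correlation). RPS4X (-0.48), RPS23 (-0.47), RPS13 (-0.32) and RPL34 (-0.48) were examples, and such genes have many pseudogene copies. Mitochondrial DNA encoded genes had 0 up and 10 down of 15 (median -0.36; camera adjusted p = 0.0246; adjusted p = 0.85 with an estimated correlation), including MT-ND5 (-0.54), MT-ND1 (-0.24), MT-RNR1 (-0.56) and MT-RNR2 (-0.61). Of 25 SWI/SNF subunits 8 rose and 7 fell (median 0.06; camera adjusted p = 0.922), with SMARCC1 (-0.75), PHF10 (-0.92) and BRD9 (0.67) among them. Of the 8 rises, 4 ended without shCTRL replicate 3, those of SMARCD1, DPF2, BCL7B and GLTSCR1 (edgeR adjusted p 0.065 to 0.22), as did the fall of SS18L1 (0.12). The same 5 calls ended without shCTRL_SMARCB1+ replicate 3 (edgeR adjusted p 0.064 to 0.16). SMARCD1 and DPF2 also lost theirs with RLE or upper quartile scaling, no filter, the strict filter, only the groups compared or protein-coding genes alone (edgeR adjusted p 0.054 to 0.26). With GC-content offsets those of SMARCD1 (edgeR adjusted p = 0.082), BCL7B (0.67) and GLTSCR1 (0.54) ended. GLTSCR1 lost its call too with upper quartile scaling (edgeR adjusted p = 0.051), protein-coding genes alone (0.071) or the GC slope covariate (0.074), and BCL7A without a filter (0.071) or with only the groups compared (0.058). Without any 1 of several other libraries SMARCD1, DPF2, SS18L1, BCL7A and GLTSCR1 had edgeR adjusted p-values of 0.052 to 0.12. Adjusted over the list alone, the counts of the lists in this comparison differed by at most 3 genes from those given.

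GC-content offsets ended the camera calls of mitochondrial DNA encoded genes (adjusted p = 0.276), HOX genes (0.153), epithelial genes (0.0636), hypoxia genes (0.068), inflammatory genes (0.776), Hedgehog and Wnt targets (0.44) and endothelial markers (0.0974). By camera they gave calls for cholesterol biosynthesis genes (0.0475), histone genes (0.0148) and blood and immune cell markers (0.0359), all lower, with 0.766, 0.668 and 0.39 at an estimated correlation. Camera calls also ended without shCTRL replicate 1 for MYC targets (adjusted p = 0.076) and ribosomal proteins (0.117) and without shCTRL replicate 3 for mitochondrial DNA encoded genes (0.0542). They ended without shDCAF5 replicate 3 for MYC targets (camera adjusted p = 0.057), without shCTRL_SMARCB1+ replicate 2 for MYC targets (0.0737) and ribosomal proteins (0.0774), and without shCTRL_SMARCB1+ replicate 3 for endothelial markers (0.061), inflammatory genes (0.0739) and mitochondrial DNA encoded genes (0.0672). By limma fry ribosomal proteins (adjusted p = 0.162) and mitochondrial DNA encoded genes (0.0608) did not pass.

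**Figure D3:**
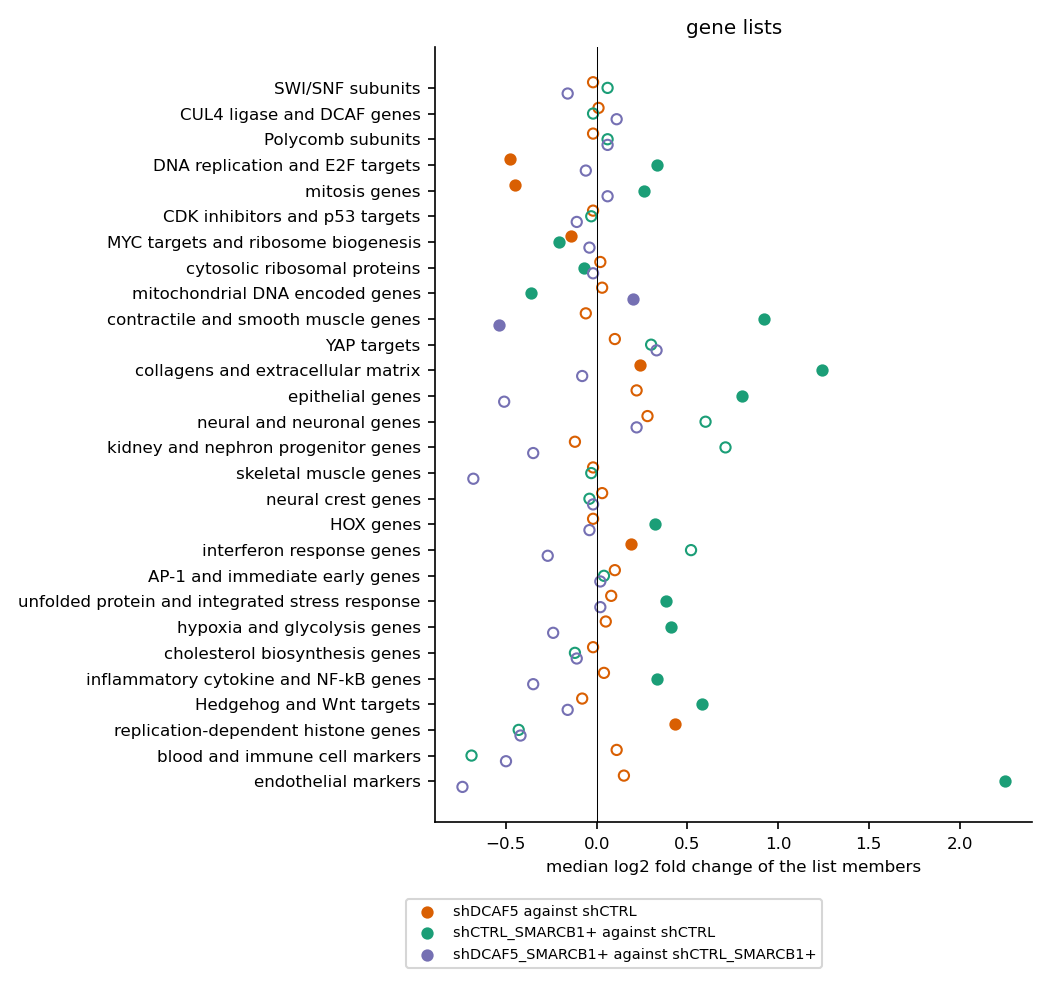
Median log2 fold change of the members of each gene list (horizontal axis, lists on the vertical axis) in 3 comparisons, shown by colour; filled points passed limma camera with its preset correlation and open points did not. Collagens and extracellular matrix lie at 1.24 with SMARCB1 re-expression, and DNA replication and E2F targets at -0.48 with DCAF5 knockdown.

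In cells that carry SMARCB1, the knockdown effect was read from shDCAF5_SMARCB1+ against shCTRL_SMARCB1+. The thioredoxin-binding TXNIP rose from 34.8 to 76.8 CPM. The phosphate transporter SLC34A2 fell from 14.6 to 4.25 CPM, the ion channel relative ANO9 from 5.84 to 0.733 CPM and NPPB, the precursor of a natriuretic peptide, from 10.7 to 1.94 CPM. Replication genes (median -0.06, camera adjusted p = 0.217, 2 up and 5 down of 48) and mitosis genes (median 0.06, camera adjusted p = 0.917, 0 up and 2 down of 44) did not pass as lists, but with GC-content offsets both were lower (medians -0.14 and -0.12, camera adjusted p = 0.00411 and 8.72e-05; adjusted p = 0.818 for both with an estimated correlation). EdgeR called 1213 genes up and 1335 down, of which 130 and 420 changed at least 2-fold.

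The largest rises were the immunoproteasome subunit PSMB9 (log2 fold change 1.77, SE 0.34, edgeR adjusted p = 0.01), ART5 (1.47), the G protein regulator RGS1 (1.40) and the protease inhibitor SERPINE2 (1.27). The cystine transporter SLC7A11 (1.15), TXNIP (1.14), the receptor guanylate cyclase GUCY2C (1.12), the axon guidance receptor ROBO1 (1.12) and MMRN1 (1.06, from 180 to 377 CPM) came next. The largest falls were ANO9 (-2.97, SE 0.42, edgeR adjusted p = 0.0022), NPPB (-2.46), ELFN1 (-1.97) and TRIM64B, 1 of a group of near-identical genes (-1.88). The heat shock protein HSPA1B, which shares reads with a near-identical copy (-1.86), the kinase PAK4 (-1.82), SLC34A2 (-1.78), SPSB3 (-1.71), the DNA glycosylase MPG (-1.69) and the protease CAPN1 (-1.66) came next. Genes called down had a median GC content of 56.2% and genes called up 44.9%, against 49.6% for all genes. Calls of these genes that ended without single libraries were those of SERPINE2 (without any shCTRL_SMARCB1+ library or shDCAF5_SMARCB1+ replicate 3, edgeR adjusted p 0.052 to 0.079; log2 fold change 0.66, 0.11 with the GC slope covariate) and SLC7A11 (shCTRL_SMARCB1+ replicate 1 or 3 or shDCAF5_SMARCB1+ replicate 3, 0.091 to 0.11). So did those of PAK4 (shCTRL_SMARCB1+ replicate 3 or shDCAF5_SMARCB1+ replicate 3, by edgeR 0.051), HSPA1B and CAPN1 (either of these or shDCAF5_SMARCB1+ replicate 2, 0.073 to 0.093). Those of ELFN1 (any library of the groups compared but shCTRL_SMARCB1+ replicate 2, edgeR adjusted p 0.054 to 0.1), SPSB3 (the same libraries or shCTRL replicate 2, 0.054 to 0.14) and MPG (any library of the groups compared, shCTRL replicate 2 or shDCAF5 replicate 2, 0.051 to 0.19) ended too.

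Camera called contractile genes lower (1 up, 6 down and 18 not passing of 25, 1 and 11 adjusted over the list alone, median -0.54, adjusted p = 0.0229; adjusted p = 0.806 with an estimated correlation). It called mitochondrial DNA encoded genes higher (1 up and 0 down of 15, median 0.20, adjusted p = 0.00989; adjusted p = 0.819 with an estimated correlation). By limma fry they had adjusted p-values of 0.0993 and 0.171. Neither camera call held with GC-content offsets (adjusted p = 0.0737 and 0.785), which instead put YAP targets (median 0.32, adjusted p = 0.0013), AP-1 genes (0.33, 0.0161) and the unfolded protein response (0.18, 0.000204) higher. With an estimated correlation these 3 had camera adjusted p-values of 0.596, 0.806 and 0.382. CNN1 (-1.51), the smooth muscle actin ACTG2 (-1.32) and leiomodin LMOD1 (-0.83) fell and PDLIM5 (1.04) rose. MT-ND6 rose (0.47, edgeR adjusted p = 0.047), while MT-RNR2 (0.30), MT-ND4L (0.29) and MT-ND2 (0.26) did not pass. The call of CNN1 ended without shCTRL_SMARCB1+ replicate 3 or shDCAF5_SMARCB1+ replicate 3 (edgeR adjusted p = 0.051), and that of LMOD1 without shCTRL_SMARCB1+ replicate 1 or 3 or shDCAF5_SMARCB1+ replicate 2 (0.053 to 0.081). That of ACTG2 ended without these, shCTRL_SMARCB1+ replicate 2 or shDCAF5_SMARCB1+ replicate 3 (by edgeR 0.051 to 0.083), and that of MT-ND6 without any library of the groups compared or shCTRL replicate 2 (0.054 to 0.17) and with the GC slope covariate (0.23, 0.079). SWI/SNF subunits again had SS18 up (0.77, edgeR adjusted p = 0.0025) and SMARCD1 down (-0.38, 0.0077). BRD9 (-0.62, 0.01), ARID2 (0.36, 0.039), SS18L1 (0.43, 0.043) and BCL7C (-0.50, 0.047) were called too. With GC-content offsets ARID2 had a log2 fold change of 0.10 (edgeR adjusted p = 0.17) and BCL7C one of 0.16 (edgeR adjusted p = 0.52). With any 1 library of the groups compared left out, ARID2 and SS18L1 had edgeR adjusted p-values of 0.063 to 0.15, and BCL7C had 0.051 to 0.19 with any 1 left out but shCTRL replicate 1 or shDCAF5 replicate 3.

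Every library of the groups compared moved the number of genes called for shDCAF5_SMARCB1+ against shCTRL_SMARCB1+ by more than 1.5 times, to 352, 607 and 275 up and 484, 818 and 363 down without shCTRL_SMARCB1+ replicates 1, 2 and 3. The counts were 646, 344 and 448 up and 704, 359 and 470 down without shDCAF5_SMARCB1+ replicates 1, 2 and 3. Of the other libraries, leaving out shDCAF5 replicate 3 gave 2378 up and 3031 down, shCTRL replicate 3 gave 1959 up, and shCTRL replicate 2 and shDCAF5 replicate 2 gave 675 and 831 down; with GC-content offsets 1044 of the 1213 and 990 of the 1335 were called among 2267 up and 2536 down. Calls ended by edgeR without a filter for SS18L1 (adjusted p = 0.055) and BCL7C (0.056), and for BCL7C among protein-coding genes (0.052) and with the GC slope covariate (0.057). By limma-voom those of MPG (adjusted p = 0.051), MT-ND6 (0.051) and BCL7C (0.054) ended.

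SMARCB1 re-expression under knockdown, shDCAF5_SMARCB1+ against shDCAF5, gave 3704 genes up and 3667 down (1767 and 1473 at least 2-fold). LAMB1 went from 5.16 to 655 CPM and SPARC from 255 to 4200 CPM, and MGST1 from 71.7 to 0.00788 CPM. The direct contrast of knockdown and re-expression, shDCAF5 against shCTRL_SMARCB1+, gave 4848 genes up and 5180 down (1571 and 2584 at least 2-fold). Highest in shDCAF5 were MGST1 (18000 times, counting interval 3230 to 710000), GRAMD3 and ZNF69 (at least 607-fold and 598-fold), EYA4, a developmental transcription cofactor (at least 440-fold), and DLGAP2 (2490 times, 688 to 20500). Highest in shCTRL_SMARCB1+ were SMARCB1 (at least 395000-fold), DIAPH2 (0.0149 against 16.7 CPM), ARSD (0.0181 against 14.7 CPM), NPFFR2 (970 times, counting interval 269 to 8010) and NLGN1 (0.0298 against 22.3 CPM).

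Whether knockdown acts differently with and without SMARCB1 was tested as an interaction, for which edgeR called 24 genes up and 140 down (9 and 87 at least 2-fold) and 2286 genes had an unadjusted p under 0.05. MSX2, a homeobox transcription factor, changed with the hairpin by -0.07 without SMARCB1 and by 1.25 with it. THBS1 (-1.26 without and -0.14 with SMARCB1), SLC7A14 (-1.09 and 0.14), PSG6 (-1.02 and 0.24) and PSG1 (-0.69 and 0.10) went lower with the hairpin in cells without SMARCB1. GALNT16 (2.12 and -0.63), CPA4 (3.68 and -0.40) and COL17A1, a collagen of the epithelial attachment to the basement membrane (1.38 and -1), went higher there. CPA4 was near the detection limit in shCTRL, so the size of its rise without SMARCB1 is uncertain. ANO9 (0.10 and -2.97) and NPPB (0.66 and -2.46) went lower with the hairpin in cells that carry SMARCB1. NPPB was higher in shCTRL_SMARCB1+ than in shCTRL by 6.43 log2 units. Its level without SMARCB1 was thus low, a fall there could hardly show, and its difference between the backgrounds is uncertain. The interaction call of PSG1 ended without shCTRL replicate 2, shDCAF5 replicate 2, any shCTRL_SMARCB1+ library or shDCAF5_SMARCB1+ replicate 1 or 2 (edgeR adjusted p 0.051 to 0.063). That of NPPB ended without any library but shCTRL replicate 1 or shDCAF5 replicate 1 (0.057 to 0.16 by edgeR), and that of ANO9 without shCTRL replicate 2 or 3, shCTRL_SMARCB1+ replicate 1 or 3 or any shDCAF5_SMARCB1+ library (0.057 to 0.097).

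Replication genes responded differently in the 2 backgrounds (interaction median 0.36, 42 of 48 members higher, 3 called up and 25 adjusted over the list alone, camera adjusted p = 3.55e-16; adjusted p = 0.345 with an estimated correlation), with GINS4 (0.57), MCM10 (0.73) and CLSPN (0.76) called. Mitosis genes had a median of 0.48, with 43 of 44 higher (3 called and 29 adjusted over the list alone, camera adjusted p = 4.5e-22; adjusted p = 0.348 with an estimated correlation), with KIF20A (0.44), KIF2C (0.54) and PRC1 (0.50) called. Lower by camera were interferon response genes (median -0.37, adjusted p = 0.00121; adjusted p = 0.348 with an estimated correlation) and histone genes (median -0.51, 17 of 17 lower, adjusted p = 3.93e-05; adjusted p = 0.451 with an estimated correlation). Epithelial genes were lower too (median -0.47, camera adjusted p = 0.0179; adjusted p = 0.451 with an estimated correlation). Of the members of these lists, 0 were called by edgeR and 4, 0 and 2 adjusted over the list alone. The histone values again cover poly(A) RNA only. Collagens and matrix genes (median -0.34, camera adjusted p = 0.0229; adjusted p = 0.806 with an estimated correlation) and hypoxia genes (-0.20, camera adjusted p = 0.0427; adjusted p = 0.751 with an estimated correlation) were lower as well. Inflammatory genes were lower (-0.34, camera adjusted p = 0.0427; adjusted p = 0.751 with an estimated correlation) and mitochondrial DNA encoded genes higher (0.13, camera adjusted p = 0.0152; adjusted p = 0.825 with an estimated correlation). With GC-content offsets these last lists had camera adjusted p-values of 0.0911, 0.092, 0.527 and 0.561, and by limma fry 0.229, 0.106, 0.116 and 0.416. FBN1 (-0.47) and COL5A1 (-1.53) were called lower and THBS1 (1.12) higher. Of 43 matrix genes 13 were higher and 30 lower. With GC-content offsets COL5A1 had an edgeR adjusted p of 0.069. By camera the offsets also put Polycomb subunits (adjusted p = 0.0477) and the unfolded protein and integrated stress response (0.0294) higher. With an estimated correlation these 2 lists had camera adjusted p-values of 0.69 and 0.668.

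Several of these interaction calls rested on single libraries. Those of replication and mitosis genes ended without shCTRL_SMARCB1+ replicate 1 or 2 or shCTRL replicate 2, with edgeR adjusted p-values of 0.059 to 0.063 for GINS4. The same held for MCM10 (0.062 to 0.12, also without shCTRL replicate 3, shDCAF5 replicate 2 or 3, shCTRL_SMARCB1+ replicate 3 or shDCAF5_SMARCB1+ replicate 2), CLSPN (0.061 to 0.11, also without these or shDCAF5_SMARCB1+ replicate 3) and KIF20A (0.061 to 0.094, also without shDCAF5 replicate 2, shCTRL_SMARCB1+ replicate 3 or shDCAF5_SMARCB1+ replicate 2 or 3). KIF2C kept its call only without shCTRL replicate 3 or shDCAF5 replicate 3 (edgeR adjusted p 0.066 to 0.14 otherwise), and PRC1 lost it without each of the 12 libraries (0.051 to 0.14). FBN1 kept its call only without shCTRL replicate 1, shDCAF5 replicate 3 or shDCAF5_SMARCB1+ replicate 1 (edgeR adjusted p 0.059 to 0.1 otherwise), and COL5A1 only without shCTRL replicate 1, shDCAF5 replicate 1 or 3, shCTRL_SMARCB1+ replicate 3 or shDCAF5_SMARCB1+ replicate 3 (0.054 to 0.083 otherwise). By camera, collagens and matrix genes had adjusted p-values of 0.07, 0.107, 0.114 and 0.0659 without replicate 3 of shCTRL, shDCAF5, shCTRL_SMARCB1+ and shDCAF5_SMARCB1+, and mitochondrial DNA encoded genes had 0.149 and 0.0749 without replicate 3 of shDCAF5 and shCTRL_SMARCB1+. Inflammatory genes had camera adjusted p-values of 0.0573, 0.102 and 0.0824 without shCTRL replicate 1, shDCAF5 replicate 3 and shCTRL_SMARCB1+ replicate 3. Hypoxia genes had 0.0537 to 0.115 by camera without shCTRL replicate 2 or 3, shDCAF5 replicate 3, shCTRL_SMARCB1+ replicate 1 or 3 or shDCAF5_SMARCB1+ replicate 1 or 2, and 0.053 with RLE and 0.0547 with upper quartile scaling. By limma-voom the interaction calls of NPPB (adjusted p = 0.11), ANO9 (0.059) and PRC1 (0.054) ended. By edgeR those of KIF20A (adjusted p = 0.11), KIF2C (0.077), PRC1 (0.1) and FBN1 (0.083) ended without a filter, that of KIF2C with the strict filter (0.065) and that of PRC1 with RLE (0.052). With the replicate block, edgeR interaction calls ended for GINS4 (adjusted p = 0.07), MCM10 (0.1), CLSPN (0.14), KIF20A (0.11), KIF2C (0.14) and PRC1 (0.16). They ended there too for SLC7A14 (edgeR adjusted p = 0.051), PSG1 (0.068), NPPB (0.087), ANO9 (0.1), COL5A1 (0.064) and FBN1 (0.099).

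**Figure D4:**
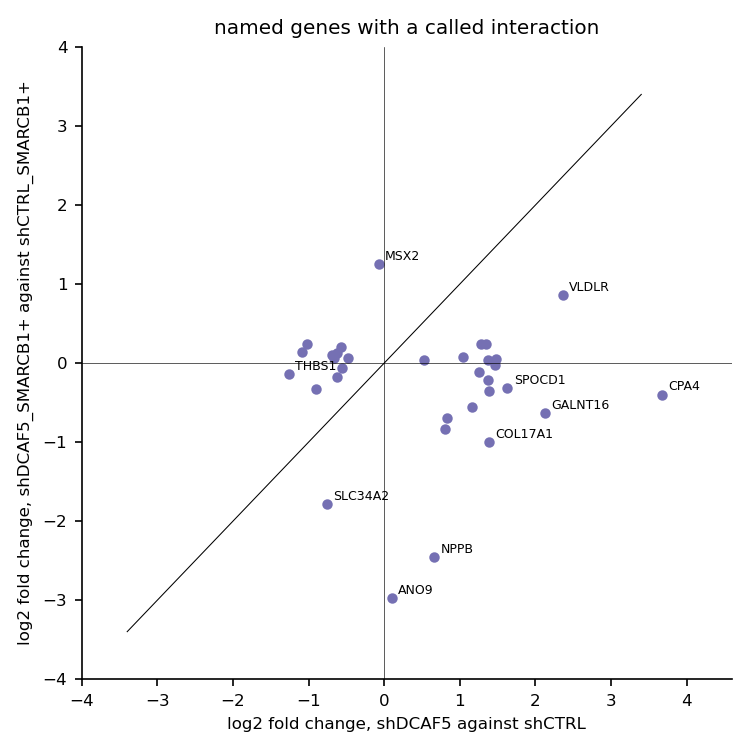
Log2 fold change with shDCAF5 in cells without (horizontal axis) and with SMARCB1 (vertical axis); each point is 1 of the named genes called for the interaction, and the diagonal marks equal effects. GALNT16 lies at 2.12 and -0.63, and MSX2 at -0.07 and 1.25.

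Genes called lower were 85.4% of the interaction calls, and 64.1% with GC-content offsets (424 up and 757 down), 83.4% with RLE and 77.6% with upper quartile scaling. Without shCTRL replicate 2, shDCAF5 replicate 2 or shCTRL_SMARCB1+ replicates 1, 2 or 3 there were 6, 10, 6, 8 and 7 genes up and 51, 70, 84, 85 and 83 down; without shDCAF5_SMARCB1+ replicates 1 or 2, 14 and 11 up, and without shCTRL replicate 3 or shDCAF5_SMARCB1+ replicate 2, 86 and 87 down.

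How far knockdown and re-expression move the same genes was read from the calls they share. Both raised 373 genes, among them MATN2 (log2 fold change 1.47 with knockdown and 2.54 with SMARCB1), ATP8B1 (1.39 and 1.66), ART5 (1.81 and 1.38), ARHGEF3 (1.37 and 1.33) and the chondroitin sulfotransferase CHST11 (1.28 and 2.43). Others were IRAK2, of interleukin signalling (1.26 and 1.44), the membrane protein STOM (1.34 and 1.16), CACNG4 (1.16 and 1.10), TXNIP (1.07 and 3.70) and the laminin chain LAMA3 (1.04 and 1.70). Both lowered 161 genes, among them PSG6 (-1.02 and -2.03), SRCRB4D (-0.99 and -1.06), DRAXIN (-1.53 and -0.66), PSG1 (-0.69 and -1.07) and the acetyltransferase NAA30 (-0.86 and -0.67). PSG11 (-0.62 and -1.77), YBX2 (-0.60 and -0.94), MMRN2 (-0.60 and -0.88), TMEM97 (-0.60 and -0.83) and CPEB1 (-0.59 and -0.76) fell with both as well. Another 174 genes rose with knockdown and fell with SMARCB1, and 171 did the reverse. Camera called replication and mitosis genes lower with knockdown and higher with SMARCB1, but with an estimated correlation neither (adjusted p = 0.19 and 0.348 with knockdown, 0.751 and 0.806 with SMARCB1).

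Independent lists of these sizes would share 186 genes up, 124 down, and 173 and 133 in opposite directions. Both contrasts use the same shCTRL libraries, so part of the excess may come from them. Across genes the fold changes correlated at 0.142, against 0.455 (-0.113 to 0.756) in 20 simulations of unchanged groups, with a covariance of 0.098 against 0.031 (-0.01 to 0.077). The simulated groups hold no real changes, so the observed and simulated correlations are not on 1 scale. With the SMARCB1 effect taken from shDCAF5_SMARCB1+ against shDCAF5, which shares libraries with the opposite sign, the correlation was -0.082, against -0.492 in the simulations, and the covariance -0.056 against -0.039 (-0.139 to -0.003). With GC-content offsets the covariances were 0.115 against 0.025 (0.021 to 0.029) and -0.054 against -0.024 (-0.029 to -0.02). The former was higher and the latter lower than in any simulation, so they do not point 1 way. With the strict filter the correlation was -0.028 instead of 0.142. Shared rises numbered 180 without shCTRL replicate 2, 236 without shDCAF5 replicate 1 and 195 without shDCAF5 replicate 2, and shared falls 50, 90 and 59 without these and 106, 98 and 105 without shCTRL replicate 3, shCTRL_SMARCB1+ replicate 1 and shCTRL_SMARCB1+ replicate 2. NAA30 kept its knockdown call only without shCTRL replicate 1, shDCAF5 replicate 1 or shDCAF5_SMARCB1+ replicate 1 or 3 (edgeR adjusted p 0.05 to 0.083 otherwise) and its SMARCB1 call ended without shCTRL replicate 3 or shCTRL_SMARCB1+ replicate 1 or 3 (0.069 to 0.094). MMRN2 lost its knockdown call without shCTRL replicate 1 or shDCAF5 replicate 2 (0.055 and 0.067), and YBX2 with GC-content offsets (0.13).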

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

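The tests of GC slopes, of GC content bias in replication and mitosis genes, of an effect alike in both backgrounds, and of the splits that kept the real groups in neither background were chosen only after the result was seen, as were the GC-content corrections.

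The interaction is listed here because the effect of the DCAF5 hairpin differed, by edgeR, between cells with and without SMARCB1, for 24 genes upward and 140 downward. Genes that responded higher in cells with SMARCB1 were MSX2 (1.32), PSG6 (1.25), SLC7A14 (1.23), THBS1 (1.12), PSG1 (0.79), PSG11 (0.76), CLSPN (0.76), MCM10 (0.73), GINS4 (0.57), KIF2C (0.54), PRC1 (0.50) and KIF20A (0.44). Genes that responded lower were CPA4 (-4.08), NPPB (-3.12), ANO9 (-3.07), GALNT16 (-2.75), COL17A1 (-2.38), SPOCD1 (-1.95), ATP8B1 (-1.74), CACNG4 (-1.72), LMOD1 (-1.64), ARHGEF3 (-1.58), COL5A1 (-1.53), MATN2 (-1.50), VLDLR (-1.50), SLC7A8 (-1.42), IRAK2 (-1.37), LRRC15 (-1.33), STOM (-1.10), CHST11 (-1.04), SLC34A2 (-1.03), LAMA3 (-0.96) and FBN1 (-0.47). The level of CPA4 was near the detection limit in shCTRL, so the size of its difference is uncertain. That of NPPB is uncertain too, since its level was low in cells without SMARCB1 and a fall there could hardly show. Among the gene lists, limma camera called mitosis genes (median 0.48), replication genes (0.36) and mitochondrial DNA encoded genes (0.13) higher. It called replication-dependent histone genes (-0.51), epithelial genes (-0.47), interferon response genes (-0.37), collagens and matrix genes (-0.34), inflammatory genes (-0.34) and hypoxia genes (-0.20) lower. With an estimated correlation camera called none of them (adjusted p 0.345 to 0.825), and with GC-content offsets the calls of mitochondrial, matrix, hypoxia and inflammatory genes ended (camera adjusted p = 0.561, 0.0911, 0.092 and 0.527), as they did by limma fry (0.416, 0.229, 0.106 and 0.116). Camera with the offsets instead called Polycomb subunits (adjusted p = 0.0477) and the unfolded protein and integrated stress response (0.0294) higher, but neither with an estimated correlation (0.69 and 0.668).

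For the interaction, 4 of 100 splits of the libraries, the real one among them, gave as many genes (164 in the real split, 9540 at most in the others). With GC-content offsets 7 of 100 did (1181 in the real split, 6502 at most in the others). In both counts all the others kept the real hairpin groups in at least 1 background and so hold the hairpin's effect, and neither share decides whether chance is excluded. The 80 splits that kept them in neither background gave 1 gene at most, with and without the offsets. Those splits mix the hairpins within each group, which adds the hairpin's effect to the spread and can lower the count. They therefore give no chance level either. Splits with several times the real count point to a structure of the samples: 9540 and 4270 genes came with the real groups in cells with SMARCB1 and mixed groups in the others. For 9540 these were shCTRL replicates 1 and 2 and shDCAF5 replicate 3 against the rest. Swapping the hairpin labels in 1 background, which sums the effects of the hairpin, gave 3914 genes, and 6502 with the offsets.

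Replication and mitosis genes were lower with shDCAF5 in cells without SMARCB1. GC content bias as the whole cause was excluded, since the higher of the list medians was -0.47 with GC-content offsets, and a single library was excluded too, since without any 1 of the 6 libraries the median nearest to 0 was -0.37. A hairpin effect alike in both backgrounds was tested by the difference of the changes in mean log2 CPM over 92 genes. The difference was 0.37 (SE 0.07, from -0.45 without and -0.08 with SMARCB1), and 0.35 (SE 0.05) with the offsets. In these libraries this argues against an alike effect, but the SE covers only their spread, which may be technical. An alike effect joined by a difference between the cultures is therefore not excluded. Loss of DCAF5 and other differences between the cultures stay open, and cell numbers and cell cycle were not measured here.

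Fold changes of shDCAF5_SMARCB1+ against shCTRL_SMARCB1+ fell with GC content. Fewer counts in shDCAF5_SMARCB1+ replicate 3 were excluded as the cause: with all libraries thinned to the lowest total, 46384130 counts, the correlation over 16326 genes was -0.61, against -0.62 over the same genes with all counts (-0.71 over the 7511 genes of higher level). GC bias of single libraries and an effect of the hairpin cannot be told apart, because the exact permutation p of the GC slopes, 0.1, is the smallest that 3 libraries against 3 can give. Slopes also differed within groups, and a biological change of GC-rich genes was not tested.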

How the results depend on the processing

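The GC-content offsets, the GC slope covariate and, for gene lists, upper quartile scaling were tests chosen only after the result was seen.

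DCAF5 stayed lower with its hairpin under every alternative run, from -0.71 to -0.66 without and from -1.06 to -0.98 with SMARCB1 when single libraries were left out. SMARCB1 re-expression stayed called under the alternatives that gave a value, which DESeq2 did not; its folds against groups with 0 counts are bounds only. Of the values of named genes under the alternatives, 5029 kept their direction and side of the threshold, 340 lost the call, 3 gained it and 1 reversed: BCL7C in shDCAF5_SMARCB1+ against shCTRL_SMARCB1+, at 0.16 with GC-content offsets. Of those of gene lists, 470 kept the call and 88 lost it. The cause of the changes given here was not tested, except that fewer genes (strict filter) or fewer libraries enter some alternatives by construction.

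With GC-content offsets, the genes called up and down numbered 2371 and 2087 for shDCAF5 against shCTRL, 2267 and 2536 for shDCAF5_SMARCB1+ against shCTRL_SMARCB1+, and 424 and 757 for the interaction, and the shared rises and falls 1054 and 706. The GC slope covariate gave 3322 and 2779, 2276 down, 554 and 1276, and shared 1465 and 945, and for shDCAF5_SMARCB1+ against shDCAF5 5987 and 5848. With the replicate block they were 419 and 254, 469 and 586, 4 and 56, and shared 224 and 63. Of 227 results of named genes, 32 lost their call with the block. With only the groups compared, shDCAF5 against shCTRL gave 161 and 78, and shDCAF5_SMARCB1+ against shCTRL_SMARCB1+ 3081 and 3465. DESeq2 gave 830 down, 2258 and 2158, 171 and 353, and shared falls of 265. No filter gave 308 down for shDCAF5 against shCTRL. The strict filter gave 2395 up for shCTRL_SMARCB1+ against shCTRL, 864 down for shDCAF5_SMARCB1+ against shCTRL_SMARCB1+, 2012 up for shDCAF5_SMARCB1+ against shDCAF5, 2814 down for shDCAF5 against shCTRL_SMARCB1+ and 59 up for the interaction. Interaction rises were 37 with upper quartile scaling and 69 among protein-coding genes. The correlation of knockdown and re-expression was -0.028 with the strict filter and -0.082 with the SMARCB1 effect from shDCAF5_SMARCB1+ against shDCAF5. Camera with an estimated correlation called 0 lists in each of the 4 contrasts, of 112 tests of which 31 passed with the preset one; fry ended 10 of these 31 and called 24 with SMARCB1 re-expression and 5 for the interaction, and GC-content offsets 5 for shDCAF5_SMARCB1+ against shCTRL_SMARCB1+.

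Without single libraries, the genes up and down ranged from 330 to 1299 and 201 to 875 for shDCAF5 against shCTRL, 3563 to 5339 and 3405 to 4683 for shCTRL_SMARCB1+ against shCTRL, 275 to 2378 and 359 to 3031 for shDCAF5_SMARCB1+ against shCTRL_SMARCB1+, 3243 to 4163 and 2872 to 4067 for shDCAF5_SMARCB1+ against shDCAF5, 4027 to 5514 and 4088 to 6330 for shDCAF5 against shCTRL_SMARCB1+, and 6 to 29 and 51 to 125 for the interaction. The lowest came without shCTRL replicate 2, shDCAF5 replicate 2, shCTRL_SMARCB1+ replicate 3 or shDCAF5_SMARCB1+ replicate 2, and the highest without shDCAF5 replicate 3, shCTRL replicate 3 or shCTRL replicate 1. Shared rises ranged from 180 to 490, shared falls from 50 to 222 and the correlation from 0.051 to 0.285. The lists called ranged from 3 (without shCTRL replicate 3) to 7, 12 to 16, 2 to 7 (without shDCAF5_SMARCB1+ replicate 3) and 5 (without shCTRL_SMARCB1+ replicate 3) to 11 in the 4 contrasts. Depth limited genes near 0 counts, whose ratios are given with counting intervals or as bounds.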

Other observations

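The list of cleavage-stage genes, the genes lowered in both backgrounds and the test of the share of genes with a seed match were chosen only after the result was seen; the search for 3' UTR motifs and the splits of the libraries were planned before their results.

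Genes of the cleavage-stage embryo, such as ZSCAN4 and the PRAMEF family, were lower with the hairpin in both backgrounds, although without SMARCB1 most were not called. Of 36 measured, 36 were lower in shDCAF5 than in shCTRL (median -0.80, 12 called by edgeR, camera p = 1.55e-15, and 0.00241 with an estimated correlation), and 36 were lower in shDCAF5_SMARCB1+ than in shCTRL_SMARCB1+ (median -1.63, 31 called by edgeR, camera p = 3.99e-23, and 0.000631 with an estimated correlation). ZSCAN4, which marks such cells, went from 4.24 to 1.75 CPM without and from 4.89 to 1.54 CPM with SMARCB1, and KHDC1L from 2.44 to 1.13 and from 4.88 to 1.17 CPM. LEUTX and CCNA1 did not pass without SMARCB1 (edgeR adjusted p = 0.37 and 0.38). In shCTRL_SMARCB1+ against shCTRL the list had a median of 1.24, with 29 of 36 higher and 7 lower (24 up and 2 down by edgeR, camera p = 3.36e-05, and 0.0531 with an estimated correlation). RFPL4B, 1 of the 2 called lower, went from 769 to 4.53 CPM. Many members are near-identical copies that share reads, so their number is uncertain. The list was written after the data were seen and the p-values were not adjusted for that choice, so they are no independent test. A later camera scan of 186 gene symbol families gave PRAMEF adjusted p-values of 1.74e-05 without and 4.36e-07 with SMARCB1. With an estimated correlation these were 0.493 and 0.349.

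Genes that moved 1 way with the hairpin in both backgrounds, which share no libraries, numbered 307 up and 261 down by edgeR, where independent lists would share 50 and 39; 35 moved in opposite directions, where 91 would. TMED4 (log2 fold change 1.01 without and 1.05 with SMARCB1) and DYNLRB1 (1.40 and 0.97) rose in both, and TNNT2 (-1.37 and -1.40), PITHD1 (-1.15 and -1.23), DRAXIN (-1.53 and -1.07) and TIMMDC1 (-1.06 and -1.14) fell in both.

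For the genes lowered in both backgrounds, GC content bias as the whole cause was excluded, since 83.5% of those with a GC value were called lower in both with GC-content offsets. A candidate explanation for part of them is a seed match of the hairpin in their 3' UTRs, as small RNAs pair. The lower permutation limit was passed by 33 sequences of 7 bases without SMARCB1 and by 13 with it, and 8 passed in both comparisons. TGTCCGA had the lowest score in each comparison (z = -7.95 and -8.99, limits -4.54 and -4.58). A single seed would give neither the 3 of these 8 that share no 4 bases with TGTCCGA (GGATCAC, TAACACA and GCACTCC) nor GTCGCCC, which passed the upper limit in both (z = 5.05 and 4.88). TGTCCGA was in 7.88% of the lowered genes with a 3' UTR, DRAXIN, TIMMDC1, PANX1 and JUN among them, against 1.4% of other genes, and its 6 bases GTCCGA were in 17.8%, against 4.15%, which excludes these 6 bases in most of the lowered genes; any of the 8 sequences was in 42.3%, against 30.2% of other genes. A guide against DCAF5 should match DCAF5 itself, but TGTCCGA was in 0 of 9 DCAF5 transcripts while GTCCGA was in 5 of 9 and AGTCCGA and AAGTCCG were found too, and the hairpin sequence is not given in the sources used here, so this stays a hypothesis and loss of DCAF5 stays open.

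Splits of 3 libraries against 3 are too few for a share under 0.05. Every split but the real one also mixes the compared groups, which adds their difference to the spread, so its count is no chance level. For shDCAF5 against shCTRL the real split gave 1303 genes and another gave 6619, so 2 of 10 gave as many. That other split set shCTRL replicates 1 and 2 and shDCAF5 replicate 3 against the rest, with mean GC slopes of 0.128 and -0.28, which points to a structure of the samples. With GC-content offsets the real split gave 4458 genes and the highest other 1118, so 1 of 10 gave as many. In each of the other comparisons 1 of 10 gave as many, with and without the offsets. The real and highest other counts were 8684 and 0 for shCTRL_SMARCB1+ against shCTRL (10803 and 0 with offsets), 2548 and 0 for shDCAF5_SMARCB1+ against shCTRL_SMARCB1+ (4803 and 0), 7371 and 0 for shDCAF5_SMARCB1+ against shDCAF5 (10405 and 0) and 10028 and 0 for shDCAF5 against shCTRL_SMARCB1+ (11542 and 1).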
